A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

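Fission yeast of strain ASP167 was grown in minimal medium from single colonies, and thiamine and the auxin NAA were added to the cultures to stop transcription of spt5 and to degrade its protein, per the labels' protocols. RNA was labelled with 4-thiouracil at 5 mM for 10 min at 0, 2.5 and 4.5 h, the labelled RNA was purified, and libraries were made with the Ovation Universal RNA-Seq system, per the labels' protocols. The labels call the 2 libraries of each time point biological replicates. The assembly ASM294v2 and the tools STAR 2.3.0 and SAMtools are named in the submitters' processing notes; the counting tool, its strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited files hold whole-number counts of reads per transcription unit, not normalised, 1 file per library. A deposited table from the authors gives the 5484 units with their coordinates, class, genes and introns, and kinetic estimates such as a half-life and a synthesis time per unit. The authors' deposited kinetic scores state no time unit, so they were used here only to rank units. A unit can hold several genes: 365 are multicistronic.

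The coordinates of the units were checked against the reference genome given for this work before any sequence was taken from it: 5028 of 5062 gene identifiers (99.3%) matched, all on the same chromosome and overlapping the annotated gene, and 4894 of 4912 introns (99.6%) began and ended with the usual splice site bases. Gene symbols come from that reference. A noncoding unit was called antisense if it overlapped a coding unit on the other strand by at least 1 base.

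Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: filterByExpr by time point (5208 units kept, 276 left out), TMM scaling, 1 quasi-likelihood fit with robust estimation over all 6 libraries with time point as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The fit leaves 3 residual degrees of freedom, and 2 with 1 library left out. Every adjusted p of a single unit comes from this test unless another tool is named, and all tests are two-sided. Gene lists and classes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, for lists with at least 4 tested units. Adjustment was over 99 tests of 33 lists and, separately, over 54 tests of 18 classes in the 3 comparisons. By camera 26 list tests and 31 class tests passed. With an estimated correlation 0 and 0 passed, the lowest adjusted p being 0.491 and 0.174. At an unadjusted p under 0.05 there were 6 and 12 such tests, and by fry 22 and 12 passed. Camera with an estimated correlation was hard to pass here even where the estimate was low. Ribosome biogenesis between 2.5 and 4.5 h had an estimate of -0.001, under the preset 0.01, yet its camera adjusted p went from 8.94e-08 to 0.491. For such a list, failing that version does not show that correlation between genes accounts for the preset result. Estimates ranged from -0.103 for glucose-repressed genes to 0.97 for glycolysis genes. They were 0.528 for the proteasome, 0.607 for core stress, 0.457 for histone and 0.509 for Pap1 genes. Where the estimate was far above the preset 0.01, the preset camera p may be too low. Members of a list were also counted after adjustment over the list alone. Of 34 lists, the Tf2 retrotransposon list had 0 units in the table and was not tested. Medians of lists and classes are of edgeR log2 fold changes. Shares of reads were compared with an exact permutation test, sense and antisense changes with 10000 random re-pairings, and bootstrap intervals use 2000 draws. Correlations, matching and figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

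Named units follow a fixed rule. It takes spt5 and the genes of the strain's other modifications, then, for each time against 0 h, the 8 units with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, a mean count of at least 50, both treated libraries on the same side of both 0 h libraries, and a symbol. For 4.5 h against 2.5 h it takes 5 and 5, for noncoding units at 4.5 h 3 and 3, and from each list the 3 members with the largest change at 4.5 h, or the 2 with the lowest p if none passed. In all 104 units are held by name. The grouping, the main test, the lists, the naming rule and the alternatives were chosen before the data were examined. Units named outside the rule are marked where they appear.

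The depth was 11525663 to 35673601 counts per library, with a median count per unit of 636 in the shallowest library. The 2 libraries of a time point differed by more than sampling noise (chi-square per unit 939, 83.2 and 24.6 at 0, 2.5 and 4.5 h), so none was treated as a repeat deposit of the other; this does not bear on whether they came from separate cultures. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals, upper-quartile scaling, scaling from coding units, no filter and a stricter one (5 CPM in 2 libraries), only the time points compared, a replicate block, a prior count of 0.5, shares of reads without the 10 units with the most reads, an overlap of at least 50% for antisense units, and leaving out each library in turn. The procedure was tested on simulated counts for 4.5 h against 0 h over 5184 units, of which 200 were changed: 26.3% of units changed 2-fold and 92% of those changed 4-fold were recovered, with 118 true and 12 false calls. The matching of antisense to coding units was tested on 259 pairs at 2.5 h, where simulated offsets of 1 and 0 gave 1.06 and 0.06. The absolute amount of RNA was not analysed here.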

Results

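Newly made RNA was sequenced from the fission yeast Schizosaccharomyces pombe before and during depletion of Spt5, a conserved elongation factor of RNA polymerase II. In the haploid h- strain used, spt5 was transcribed from the thiamine-repressible promoter Pnmt81 and its protein carried a degron, a tag that directs destruction of the protein when an auxin is added to cells that make the plant receptor TIR1. Thiamine and the synthetic auxin NAA were added at 0 h, and RNA was labelled with 4-thiouracil for 10 min at 0, 2.5 and 4.5 h, so that the purified RNA is enriched for transcripts made within the pulse. There were 2 biological replicates at each of the 3 time points, 6 libraries in all. The counts assigned to transcription units added up to 29268534 and 35673601 in the 0 h libraries, 17794017 and 11525663 at 2.5 h, and 13598877 and 14559076 at 4.5 h. Of 5484 units in the deposited table, 5208 had enough counts to be tested, of which 4437 were protein-coding and 749 were noncoding. A count of 0 allows up to 3 counts, which is 0.26 CPM of the library total in the shallowest library; this floor and the intervals of counts cover counting error only. No spike-in was used here, so each change is relative to the other transcripts of the same library. All libraries came from a single strain without an untreated time course, so Spt5 loss, thiamine, NAA and time in culture cannot be told apart. The 2 libraries of 0 h differed more than the others: 630 units (12.1%) differed at least 2-fold between them, against 104 and 85 units between the replicates of 2.5 and 4.5 h.

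The spt5 transcript itself fell at both times, which checks the labels of the libraries. The unit of spt5 (SPAC23C4.19, chromosome I, 1063747 to 1066940 on the plus strand, ASM294v2) had 883 ± 229 CPM (counts scaled to a common library total, with TMM scaling) at 0 h, 114 ± 8.92 at 2.5 h and 95.2 ± 4.21 at 4.5 h (SD, n = 2 each). The log2 fold change was -2.95 (SE 0.22, adjusted p = 0.00468) at 2.5 h and -3.21 (SE 0.23, adjusted p = 0.00383) at 4.5 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without replicate 2 of 2.5 h the value at 2.5 h was -2.88 with an adjusted p of 0.0694. The 4.5 h level was -0.26 on the log2 scale relative to 2.5 h (adjusted p = 0.443). Genes that thiamine represses fell with it: all 5 measured members of the fixed list fell at both times, 5 of 5 also adjusted over the list alone. They were thi2 and thi4, which act in thiamine synthesis, the thiamine transporter gene thi9, the vitamin transporter gene bsu1 and the acid phosphatase gene pho4. At 4.5 h their log2 fold changes were -5.73, -3.80, -4.64, -3.91 and -3.85. The list passed limma's camera test against all other units (adjusted p = 1.7e-05 at both times, and 0.622 with an estimated correlation). No list passed with an estimated correlation, not even this one with all 5 members down. Failing that version therefore does not show that a list is unchanged. Passing only with the preset correlation is weak support where the estimate is high. The strain carries extra skp1 sequence in the TIR1 fusions and its ade6 locus is altered; skp1 was at -0.33 and ade6 at -0.73 at 4.5 h, neither past the threshold. Both values depended on the 0 h libraries. Without replicate 1 of 0 h skp1 was at 0.45 and ade6 at -0.37, and without replicate 2 of 0 h they were at -0.86 (adjusted p = 0.00888) and -1.07 (adjusted p = 0.00475). For nmt1, from which the promoter derives, and ura4, deleted in the strain, 0 units were found in the deposited table.

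**Figure D1:**
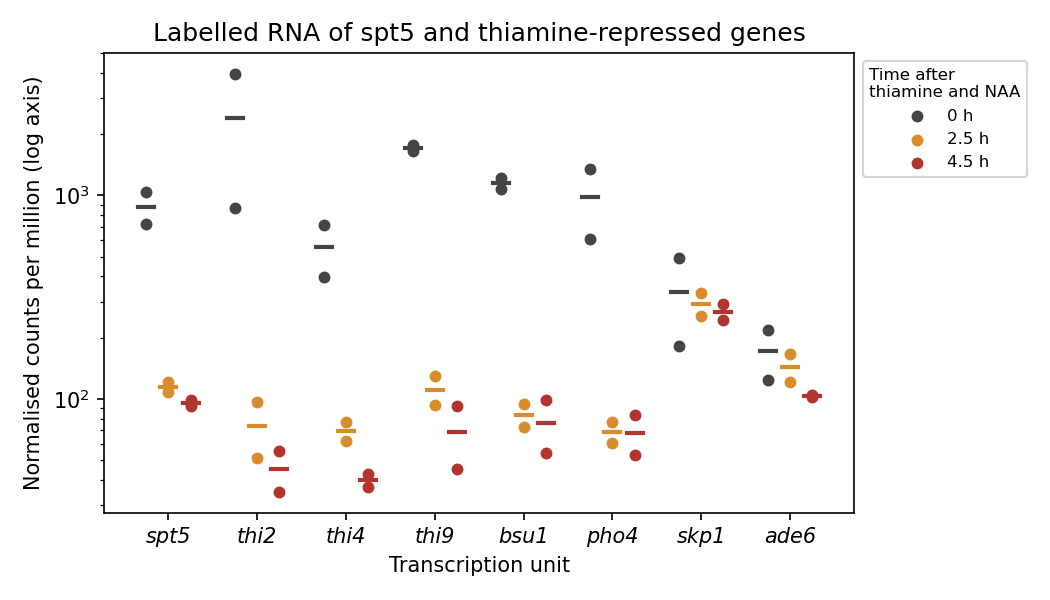
Normalised CPM (log axis) of the spt5 unit, 5 thiamine-repressed genes, skp1 and ade6; each point is 1 library, each bar the mean of the 2 libraries of a time point, and colour gives the time after thiamine and NAA. The spt5 mean lies at 883 at 0 h, 114 at 2.5 h and 95.2 at 4.5 h, while the 2 libraries of 0 h lie at 491 and 182 for skp1 and at 218 and 124 for ade6.

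The first comparison asks how newly made RNA differed 2.5 h into depletion. At 2.5 h 642 units rose and 266 fell, out of 5208. Of 749 noncoding units 301 rose and 5 fell, whereas 335 of 4437 coding units rose and 261 fell. Of 34 proteasome units 15 fell and of 11 core histone units 6 rose. Neither list passed camera with an estimated correlation (adjusted p = 0.692 and 0.772). Neither passed fry, a test of whether the units of a list move one way on balance (adjusted p = 0.065 and 0.0723). Among units with a gene symbol and a mean count of at least 50, the snoRNA units snoR69b, snoR56 and snr79 were within the 8 largest rises. Noncoding units were over-represented among the higher calls, with an odds ratio of 8.11 (Fisher's exact test across units, p = 1.91e-104). That test treats units as independent, and the class did not pass camera with an estimated correlation (adjusted p = 0.2 with an estimated correlation).

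Among units with a gene symbol and a mean count of at least 50, the largest rises were snoR69b (4.19, SE 0.69), cmt2 (3.40, SE 0.42) and snoR56 (3.28, SE 0.28). After these came the long noncoding RNA nam3 in a unit shared with SPNCRNA.532 (3.25), hen1, which encodes an RNA methyltransferase (2.99), fau1 (2.77), the snoRNA snr79 (2.64) and gal10, of galactose metabolism (2.63). The largest falls among these units were the thiamine genes thi2 (-5.03), thi9 (-3.94), pho4 (-3.82), bsu1 (-3.78), thi201 (-3.69) and thi4 (-3.01), then spt5 and mts4 (-1.72, SE 0.14). The last of these encodes a regulatory subunit of the proteasome; its unit went from 697 ± 30.2 to 212 ± 1.95 normalised CPM (SD, n = 2). Of the 34 units of the proteasome list, 15 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.58. The list passed camera with an adjusted p of 3.82e-09 (adjusted p = 0.692 with an estimated correlation), and pre6, of the proteasome core, was at -1.38 (adjusted p = 0.00534). Of the 59 ribosome biogenesis genes 7 fell and 2 rose (3 and 2 adjusted over the list alone), with a median of -0.26 and a camera adjusted p of 0.00189 (adjusted p = 0.622 with an estimated correlation).

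Of the 11 core histone genes 6 rose and 0 fell at 2.5 h (8 and 0 adjusted over the list alone), with a median of 0.84 and a camera adjusted p of 0.0116 (adjusted p = 0.772 with an estimated correlation). The histone H4 gene hhf3 was at 0.84 and the H2A gene hta1 at 0.91; hta1 overlaps htb1 on the other strand, and histone gene copies are near-identical, so single histone values are uncertain. In the core environmental stress list of 21 genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.67 and a camera adjusted p of 0.0142 (adjusted p = 0.93 with an estimated correlation). The small heat shock gene hsp9 rose by 1.64. The median of the stress list also differed between the 2 libraries of 0 h, by -0.60 (replicate 1 minus 2), and without replicate 1 of 0 h its median on the log2 CPM scale used for camera was 0.31 in place of 0.66 (camera adjusted p = 0.418). Of the 19 subunits of RNA polymerases I and III, 2 fell and 0 rose (1 and 0 adjusted over the list alone; median -0.36, camera adjusted p = 0.0258, adjusted p = 0.628 with an estimated correlation). The polymerase list did not pass without replicate 1 of 0 h (0.0522) or replicate 1 of 2.5 h (0.0501). Of 20 actin and cytokinesis genes 1 fell (also 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.0442, adjusted p = 0.622 with an estimated correlation). It was ain1, of the actin crosslinker alpha-actinin, at -0.83, and the list did not pass without replicate 1 of 0 h (0.127) or replicate 1 of 2.5 h (0.0512). Without replicate 2 of 0 h its log2 CPM median was -0.46 in place of -0.24. The actin list also did not pass camera with the stricter filter. By fry core stress genes (adjusted p = 0.147), RNA polymerases I and III (0.0516) and actin genes (0.0723) did not pass at 2.5 h. Ribosome biogenesis (0.0223) and thiamine-repressed genes (0.0228) passed fry. Of 72 meiotic genes 11 rose and 0 fell, also adjusted over the list alone, but the list did not pass camera (median 0.15, adjusted p = 0.164). The transcription factor gene mei4 was at 1.09 (0.72 without replicate 1 of 0 h) and mug2 at 1.86. The septum genes cdc15 (1.03) and chs2 (1.35) rose and eng1 (-0.84) fell, in a list of 21 mitosis and septation genes with 3 rises and 1 fall (also 3 and 1 adjusted over the list alone). The 141 units of ribosomal proteins, whose copies are near-identical in sequence, had a median of -0.25 by edgeR. On the log2 CPM scale used for camera their median and mean were both 0.20. Their levels differed by a median of 2.43 on the log2 scale between the 2 libraries of 0 h, and 2 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.939; at an unadjusted p under 0.05 there were 3 units by edgeR, and DESeq2 called 2 higher and 1 lower).

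The count at 2.5 h depended on the libraries in the fit. With only the libraries of 0 and 2.5 h it was 420, against 908 with all libraries. Each of the 908 calls that was still tested kept its direction with any 1 library left out. That was likely from the start, since the calls were chosen in these same data. The share of rises among the calls, 70.7% with all libraries, depended on single libraries too. Without replicate 1 of 0 h 1171 units rose and 1044 fell (52.9% higher), and without replicate 2 of 0 h 1085 rose and 1075 fell (50.2%). The count was 2215 without replicate 1 of 0 h, 2160 without replicate 2 of 0 h, 183 (90.2% higher) and 1 without replicate 1 and replicate 2 of 2.5 h, and 373 and 383 (85.0% and 85.1% higher) without replicate 1 and replicate 2 of 4.5 h; the 1 remaining unit, SPAC9G1.14 (6.65, adjusted p = 0.0173), is named after its values were seen.

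The second comparison asks the same at 4.5 h. At 4.5 h 526 units rose and 406 fell (56.4% higher), but falls were the more frequent with DESeq2 size factors (453 and 472, 49.0% higher), with library totals (381 and 432, 46.9%) and by DESeq2 (601 and 633, 48.7%). Of 749 noncoding units 197 rose and 36 fell (odds ratio among the rises 4.48, Fisher's exact test across units, p = 7e-45; camera adjusted p = 0.344 with an estimated correlation). Of the coding units 323 rose and 369 fell. The units that rose included 10 of 11 histone, 9 of 21 core stress, 5 of 21 heat shock and 6 of 13 Pap1 oxidative stress genes. Those that fell included 4 of 16 iron and copper, 4 of 13 mating and 7 of 57 amino acid synthesis genes. With an estimated correlation none of these lists passed camera (lowest adjusted p = 0.622), a version of the test that no list passed here. By fry core stress (adjusted p = 0.0947), Pap1 (0.0592) and amino acid synthesis genes (0.478) did not pass. Histone (0.0228), heat shock (0.0251), iron and copper (0.0368) and mating genes (0.0368) passed fry. The lists overlap. The genes hsp9 and hsp16 are in the core stress and heat shock lists. The genes srx1, ctt1 and gst2 are in the core stress and Pap1 lists.

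Among units with a gene symbol and a mean count of at least 50, the largest rises were snoR69b (4.21, SE 0.69), snr79 (3.04), hsp9 (2.97), snoR56 (2.94), nam3 (2.70), cmt2 (2.64), obr1 (2.47) and the proteinase inhibitor gene pbi2 (2.29, SE 0.19). The largest falls among these units besides spt5 and the listed thiamine genes were thi201 (-4.09) and alr2, of alanine racemase (-2.49, SE 0.28). Of the 11 histone genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.29 and a camera adjusted p of 6.35e-06 (adjusted p = 0.628 with an estimated correlation). The H2B gene htb1 was at 1.86, hta1 at 1.72 and hhf3 at 1.64. In the core stress list 9 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 1.00 and a camera adjusted p of 0.00684 (adjusted p = 0.907 with an estimated correlation). Without replicate 1 of 0 h the log2 CPM median was 0.58 in place of 1.00 (camera adjusted p = 0.169). The gene hsp9 went from 294 ± 18.8 to 2310 ± 96.6 normalised CPM (SD, n = 2), hsp16 rose by 2.15, and tms1 was the member that fell (-1.68). Of 21 heat shock and chaperone genes 5 rose and 0 fell (8 and 0 adjusted over the list alone), among them the Hsp70 gene ssa1 (1.25). The median was 0.34 and the camera adjusted p 0.0372 (adjusted p = 0.692 with an estimated correlation; 0.0835 without replicate 1 of 0 h).

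Of 13 genes of the Pap1 oxidative stress response 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.64 and a camera adjusted p of 0.0153 (adjusted p = 0.828 with an estimated correlation). Without replicate 1 of 0 h the log2 CPM median was 0.27 in place of 0.67 (camera adjusted p = 0.193). The peroxiredoxin gene tpx1 was at 1.92, the sulfiredoxin gene srx1 at 1.67 and obr1 at 2.47; the list's median differed by -0.44 between the 2 libraries of 0 h. Of 16 iron and copper genes 4 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.64 and a camera adjusted p of 0.000578 (adjusted p = 0.622 with an estimated correlation). They included the copper transporter genes ctr4 (-1.43) and ctr5 (-1.58) and vht1 (-2.48; -1.64 without replicate 1 of 0 h), which encodes a biotin transporter. Of 13 mating genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -1.01 and a camera adjusted p of 0.0142 (adjusted p = 0.622 with an estimated correlation). Without replicate 1 of 0 h the log2 CPM median was -0.60 in place of -1.03. The pheromone signalling genes gpa1 (-1.53) and ste4 (-1.79) fell and the M-factor gene mfm3 rose (2.97) from 0.336 ± 0.19 normalised CPM (SD, n = 2). Of 57 amino acid synthesis genes 7 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.39 and a camera adjusted p of 0.00697 (adjusted p = 0.965 with an estimated correlation). The glutamate synthase gene glt1 was at -1.37, lys1 at -1.36 and arg4 at -1.21. The list differed by a median of 0.77 between the libraries of 0 h, and its log2 CPM median of -0.31 was 0.00 without replicate 1 of 0 h (camera adjusted p = 0.723) and -0.78 without replicate 2. Subunit genes of RNA polymerase II had 4 rises and 0 falls among 12 (5 and 0 adjusted over the list alone; camera adjusted p = 0.11), with rpb4 at 1.21 and rpb3 at 1.14.

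For the proteasome list at 4.5 h edgeR called 0 of 34 units (0 adjusted over the list alone; 5 had an unadjusted p under 0.05, and DESeq2 called 0 higher and 1 lower). Its median was 0.03 by edgeR and its mean 0.04 on the log2 CPM scale, with camera's direction lower (adjusted p = 0.891). The median became negative with DESeq2 size factors (-0.03) and with library totals (-0.06). The count at 4.5 h was 2186 without replicate 1 (50.3% higher) and 2129 without replicate 2 of 0 h (49.0% higher), 333 and 332 without replicate 1 and replicate 2 of 2.5 h, and 108 and 48 without replicate 1 and replicate 2 of 4.5 h. Each of the 932 calls kept its direction in these fits, which was likely from the start for calls chosen in these same data. With only the libraries of 0 and 4.5 h in the fit the count was 363.

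The third comparison asks what differed between 2.5 and 4.5 h. From 2.5 to 4.5 h 174 units rose and 360 fell. Of 34 proteasome units 13 rose, of 59 ribosome biogenesis units 11, of 21 heat shock and chaperone units 5 and of 11 histone units 3. Of 749 noncoding units 88 fell and 4 rose. None of these groups passed camera with an estimated correlation (lowest adjusted p = 0.344). Among units with a gene symbol and a mean count of at least 50, agp3, opt3 and vht1, which encode transporters, were within the 5 largest falls.

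Among these units the Pol III subunit gene rpc11 rose most (1.78, SE 0.25), then hsp16 (1.43), emc5 (1.43), the Mediator gene srb7 (1.36) and hsp9 (1.33). The largest falls among them were the amino acid permease gene agp3 (-3.32, SE 0.26), the oligopeptide transporter gene opt3 (-3.16), fau1 (-3.07), the D-amino acid oxidase gene dao1 (-2.57) and vht1 (-2.56). The unit of fau1 went from 7.76 ± 1.81 at 0 h to 53.0 ± 6.38 at 2.5 h and 6.30 ± 0.0825 normalised CPM at 4.5 h (SD, n = 2). Of the 34 proteasome units 13 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.70 and a camera adjusted p of 1.91e-10 (adjusted p = 0.692 with an estimated correlation). The subunit gene pre6 was at 0.87, and mts4, outside the list, at 1.09. Of the ribosome biogenesis genes 11 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 8.94e-08 (adjusted p = 0.491 with an estimated correlation); utp24 was at 1.02 and utp16 at 0.78. Of the heat shock and chaperone genes 5 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.59 and a camera adjusted p of 2.35e-06 (adjusted p = 0.622 with an estimated correlation). Of the histone genes 3 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.64 and a camera adjusted p of 0.00022 (adjusted p = 0.692 with an estimated correlation); htb1 was at 1.02.

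Of 66 splicing factor genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 3.14e-05, adjusted p = 0.622 with an estimated correlation). Subunits of RNA polymerases I and III had 3 rises and 0 falls (7 and 0 adjusted over the list alone; median 0.35, camera adjusted p = 0.000183, adjusted p = 0.622 with an estimated correlation), and those of RNA polymerase II 1 rise, rpb4 at 1.16, and 0 falls (4 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 0.00123, adjusted p = 0.692 with an estimated correlation). The Pap1 genes had 1 rise, obr1 at 1.01, and 0 falls (3 and 0 adjusted over the list alone; median 0.37, camera adjusted p = 0.00676, adjusted p = 0.772 with an estimated correlation). Without replicate 1 of 2.5 h their log2 CPM median was 0.23. Among 25 genes of the exosome and RNA surveillance 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 0.0282, adjusted p = 0.622 with an estimated correlation; 0.0646 without replicate 1 of 2.5 h). For 22 elongation factor genes edgeR called 0 (0 adjusted over the list alone; 4 had an unadjusted p under 0.05, and DESeq2 called 0), while the list passed camera (median 0.28, adjusted p = 0.0136, adjusted p = 0.622 with an estimated correlation). For the 141 ribosomal protein units edgeR called 0 (0 adjusted over the list alone; 4 had an unadjusted p under 0.05, and DESeq2 called 2 higher and 0 lower), with a median of 0.32 and a camera adjusted p of 0.0201 (adjusted p = 0.992 with an estimated correlation). Their log2 CPM median of 0.33 was 0.08 without replicate 2 of 2.5 h (camera adjusted p = 0.249) and 0.60 without replicate 1.

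The split of 174 rises and 360 falls (32.6% higher) was 42 and 286 (12.8%) with library totals. It was 80 and 400 (16.7%) with upper-quartile scaling and 84 and 366 (18.7%) with scaling from coding units. With only the libraries of 2.5 and 4.5 h in the fit edgeR called 2009 units, among them 532 of the 534 main calls. Without any 1 of the 4 libraries of 2.5 and 4.5 h edgeR called 0 units. At an unadjusted p under 0.05 there were then 1091 and 863 without replicate 1 and replicate 2 of 2.5 h, and 817 and 796 without replicate 1 and replicate 2 of 4.5 h; with all libraries DESeq2 called 910. Without replicate 1 or replicate 2 of 0 h the count was 2020 or 2024, of which 47.7% or 49.4% were higher.

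**Figure D2:**
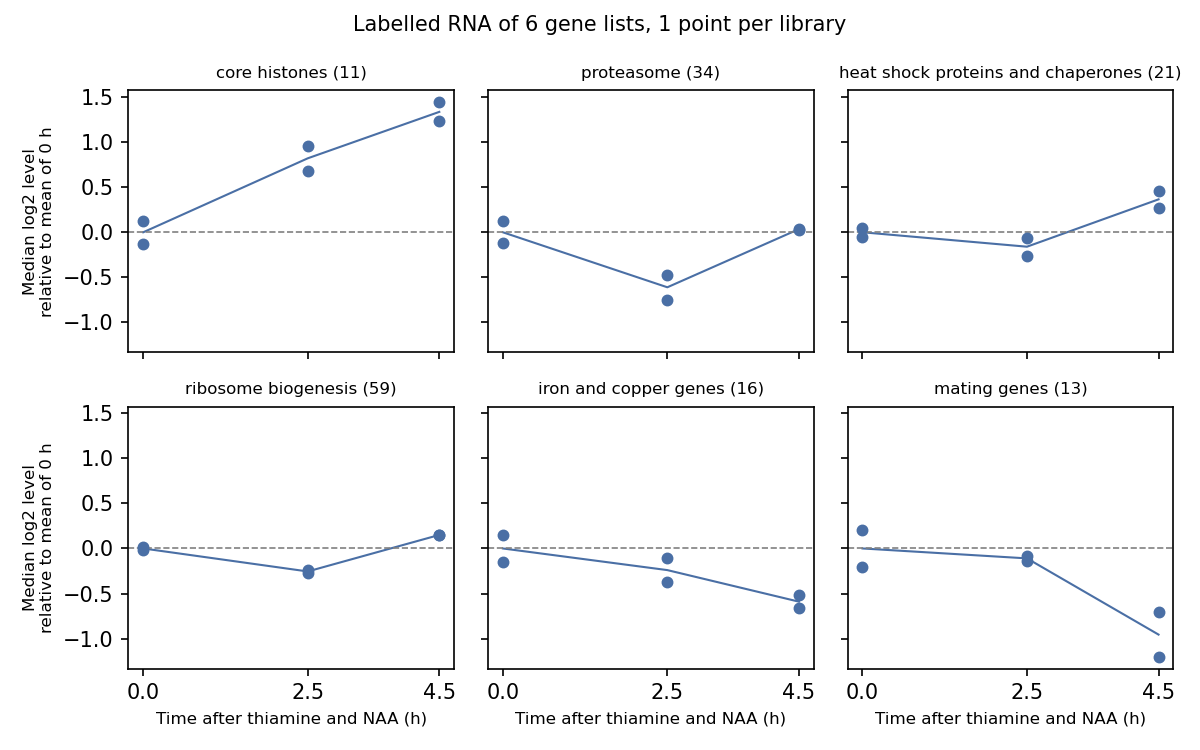
Median log2 level of 6 fixed gene lists in each library relative to the mean of 0 h, against time after thiamine and NAA in hours; points are libraries, lines join the means of the 2 libraries, and the number of units is in each title. Histone medians were 0.68 and 0.96 at 2.5 h and 1.23 and 1.44 at 4.5 h; proteasome medians were -0.47 and -0.75 at 2.5 h and 0.04 and 0.03 at 4.5 h, the last pair changing sign with DESeq2 size factors or library totals.

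Among noncoding units that overlap a coding unit on the opposite strand, rises outnumbered falls at both times. Of 413 such antisense units 217 rose and 2 fell at 2.5 h (266 and 5 adjusted over the class alone), with a median of 1.51, and 133 rose and 14 fell at 4.5 h (173 and 19), with a median of 0.88. From 2.5 to 4.5 h 2 rose and 56 fell (5 and 84), with a median of -0.59. The antisense class passed camera in the 3 comparisons, with adjusted p-values of 6.35e-34, 2.13e-14 and 5.54e-10 (adjusted p = 0.2, 0.281 and 0.344 with an estimated correlation). All noncoding units had medians of 1.08, 0.65 and -0.46, with camera adjusted p-values of 2.93e-30, 1.3e-09 and 1.13e-08 (adjusted p = 0.2, 0.344 and 0.344 with an estimated correlation). By fry, which tests whether the units of a class move one way on balance, the adjusted p of the antisense class was 0.0264 at 2.5 h, 0.0425 at 4.5 h and 0.0585 between them. Whether the counting used strand is not given in the sources used here, so antisense values are uncertain. In 468 pairs with at least 90% of the noncoding unit inside the coding unit, 418 noncoding units had 10 or more reads, and antisense reads per base were a median of 2.39% of those of the sense unit.

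Among noncoding units with a mean count of at least 50, those that rose most at 4.5 h included SPNCRNA.687 (chromosome I, 799385 to 799949, minus strand), which went from 4.10 ± 2.22 to 88.3 ± 11.3 normalised CPM (SD, n = 2; log2 fold change 4.41), and an unnamed unit on chromosome II (TU.5470, 1080678 to 1081195, minus strand; 4.38). The unit of SPCTRNAPHE.04, a tRNA gene with near-identical copies, was at 5.36 from 12 and 3 counts at 0 h. Among the same noncoding units the largest fall was that of TU.0417 (chromosome I, 1482234 to 1482628, plus strand; -4.14), which lies just upstream of the thiamine transporter gene thi9 on the same strand. After it came TU.0429 (chromosome I, 1535416 to 1535928, plus strand; -2.94) and TU.6273 (chromosome II, 3978402 to 3980709, minus strand; -2.79). As a share of counted reads, noncoding units took 1.09 ± 0.301% at 0 h, 1.68 ± 0.0976% at 2.5 h and 1.33 ± 0.0191% at 4.5 h, and antisense units 0.388 ± 0.159%, 0.684 ± 0.0764% and 0.515 ± 0.0537% (SD, n = 2). The exact permutation test of a share, 2 against 2 and two-sided, cannot give less than 0.333, which it gave for both classes at 2.5 h and for noncoding units at 4.5 h; it gave 0.667 for antisense units at 4.5 h. The difference from 0 h depended on the 0 h libraries. For noncoding units it was 0.586 percentage points at 2.5 h (0.373 without replicate 1 of 0 h). At 4.5 h it was 0.246, and 0.0331 without replicate 1 and 0.459 without replicate 2 of 0 h. For antisense units it was 0.296 points at 2.5 h (0.183 without replicate 1 of 0 h). At 4.5 h it was 0.127, and 0.0147 without replicate 1 and 0.240 without replicate 2 of 0 h.

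**Figure D3:**
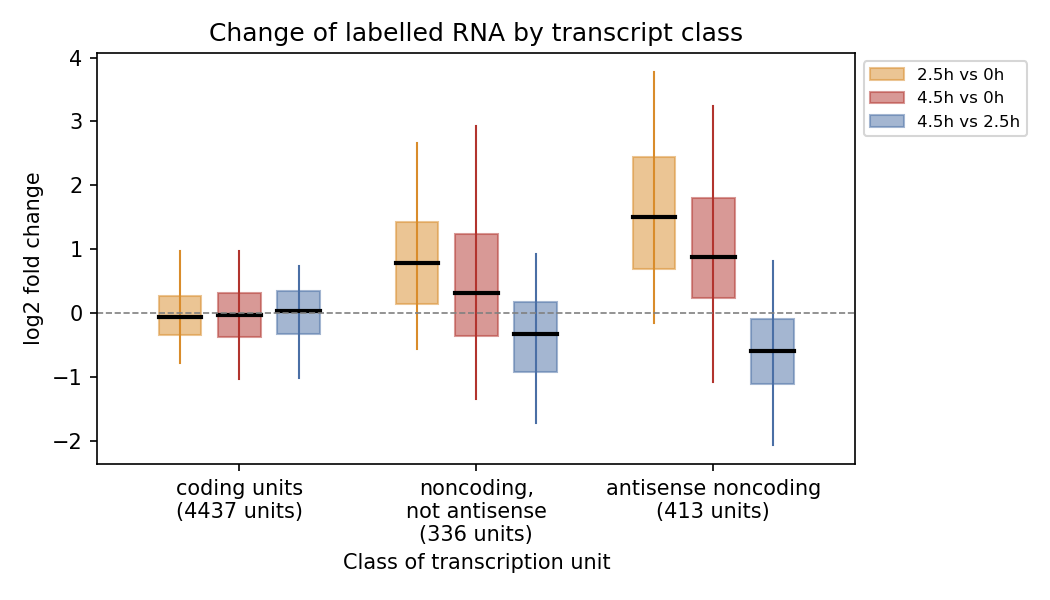
Log2 fold change of coding units (4437), noncoding units that are not antisense (336) and antisense units (413) in the 3 comparisons; boxes span the 25th to the 75th percentile, lines the 5th to the 95th, and the black bar is the median. The antisense medians lie at 1.51, 0.88 and -0.59 and the coding medians at -0.06, -0.03 and 0.04. Those of noncoding units that are not antisense lie at 0.78, 0.31 and -0.33, in the same directions as the antisense ones.

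In 425 pairs of an antisense unit and the coding unit it overlaps, the antisense member exceeded its partner by a median log2 fold change of 1.56 at 2.5 h (95% bootstrap interval over pairs 1.35 to 1.70) and 1.05 at 4.5 h (0.90 to 1.14). The antisense member rose in 225 pairs at 2.5 h and 139 at 4.5 h, and the sense member fell in 23 and 52. Both happened in 18 and 20 pairs, against 12.2 and 17.0 for independent calls. Across pairs, which are not replicates, the sense and antisense changes had a Spearman rho of -0.27 at 2.5 h (p = 0.0001, the smallest that 10000 random re-pairings can give) and 0.02 at 4.5 h (p = 0.738).

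Among 4437 coding units the change at 2.5 h had a Spearman rho of 0.02 with unit length, which became -0.22 without replicate 1 and 0.18 without replicate 2 of 0 h. It was 0.14 without replicate 1 and -0.10 without replicate 2 of 2.5 h. At 4.5 h rho was -0.14 (-0.32 without replicate 1 and 0.03 without replicate 2 of 0 h). Between 2.5 and 4.5 h it was -0.19 (-0.29 without replicate 1 and -0.08 without replicate 2 of 2.5 h). The partial rho given level and GC content was 0.11 at 2.5 h, -0.24 at 4.5 h and -0.41 between them. Of the shortest quartile of coding units (281 to 1290 bases) 126 rose and 38 fell at 4.5 h. Of the longest quartile (2679 to 16263 bases) 56 rose and 92 fell. The median of the shortest quartile at 4.5 h, 0.16, changed sign without replicate 2 of 0 h. These relations are across genes, which are not independent replicates.

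Of the units that rose, 324 did so at both times, against 64.8 for independent lists of these sizes, and of those that fell 92, against 20.7; 10 were called in opposite directions. The log2 fold changes of the 2 times had a Pearson r of 0.70 across units and a covariance of 0.453. Both use the same 0 h libraries. Unchanged groups were therefore simulated for all 6 libraries, with a single dispersion per unit at every time. They gave a mean r of 0.48 (highest 0.52) and a covariance of 0.064. The real replicates differed more at 0 h (SD of the log2 difference 0.748) than at 2.5 and 4.5 h (0.354 and 0.301). The simulated values may therefore be too low, and do not show that r exceeds what shared 0 h libraries give. With no 0 h library in common r was 0.35 or 0.45 and the covariance 0.283 or 0.343; part of the excess over independent lists may come from the shared 0 h libraries.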

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

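Of the tests of antisense units given in this part, the comparison with short-lived coding units and the comparison with sense partners as a test of strand were chosen only after the result was seen. The first took the place of sense partners, which had given 1.56, as the test of long-lived RNA.

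The results in this part stand out because the change from 2.5 to 4.5 h itself passed its test, by edgeR for units and by camera with its preset correlation for lists and classes. For units the number of calls depended on which libraries shared the fit. With all 6 libraries edgeR called 534 units. With only those of 2.5 and 4.5 h it called 2009, among them 532 of the 534. The calls did not hold when 1 of the 4 libraries of 2.5 and 4.5 h was left out, as given above. DESeq2 on all libraries called 910. The cause of the changed counts was not tested. Among stress and chaperone genes the log2 fold changes from 2.5 to 4.5 h were 1.43 for hsp16, 1.33 for hsp9, 1.21 for ssa1, 1.01 for obr1 and -1.48 for tms1. The histone genes htb1 and hhf3 were at 1.02 and 0.80, the proteasome genes mts4 and pre6 at 1.09 and 0.87, and the polymerase subunit genes rpc11 and rpb4 at 1.78 and 1.16. In ribosome biogenesis utp24 was at 1.02 and utp16 at 0.78, and the ubiquitin ligase adaptor gene cdt2 was at 1.09. Lower at 4.5 h were fau1 (-3.07), the biotin transporter gene vht1 (-2.56), hen1 (-1.62), the respiration genes atp10 (-1.41) and cox18 (-1.12), gld1 (-1.14), the myosin light chain gene rlc1 (-0.84) and the uracil permease gene fur4 (-0.73).

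Among gene lists, the median differences of log2 CPM from 2.5 to 4.5 h were 0.73 for the proteasome, 0.64 for RNA polymerase II, 0.63 for histones, 0.60 for heat shock proteins and 0.48 for ribosome biogenesis. They were 0.37 for Pap1 genes, 0.35 for RNA polymerases I and III, 0.33 for ribosomal proteins, 0.30 for splicing, 0.28 for elongation factors and 0.23 for the exosome. These medians are taken from the camera input and differ slightly from those of the edgeR fold changes in the text above. For noncoding units the median was -0.43 and for antisense units -0.58. With an estimated correlation none of these lists and classes passed camera (adjusted p from 0.344 to 0.992). By fry the proteasome (0.0592), histones (0.0766), RNA polymerase II (0.0929), Pap1 genes (0.147), ribosomal proteins (0.787), noncoding units (0.0589) and antisense units (0.0585) did not pass either. By camera ribosomal proteins did not pass without replicate 2 of 2.5 h (median 0.08; 0.60 without replicate 1), and the exosome did not pass without replicate 1 of 2.5 h (adjusted p = 0.0646), where the Pap1 median was 0.23.

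The antisense rise at 2.5 h was weighed against technical explanations. Noncoding units that are not antisense moved the same way with a smaller median (0.78 at 2.5 h) and were not part of these tests. Lower carry-over of long-lived RNA in the treated libraries would raise short-lived coding transcripts as well. Antisense units exceeded the coding units of the shortest half-lives by 1.45 (95% bootstrap interval 1.29 to 1.56). Against replicate 1 and replicate 2 of 0 h alone the excess was 1.41 and 1.48. This argues against lower carry-over as the whole cause. Intervals in this paragraph resample units or pairs of units and do not measure the spread between libraries. Low level, short length or GC content as the whole cause are argued against as well: relative to coding units matched on these, which was possible for 259 of 413 units, the median difference was 1.04 (0.86 to 1.20). Transcription running on from a coding unit upstream on the same strand may contribute, since antisense units within 500 bases of such a unit exceeded those more than 2000 bases away by 0.79 (0.38 to 1.35), although the 242 distant units still had a median of 1.40 against 2.20 for the 63 near ones. Reads of the sense gene counted in the antisense unit are argued against only if their share was equal in all libraries. With an equal share, such reads would move both members alike, and the antisense member exceeded its partner by 1.56 (1.35 to 1.70). A share that differed between the libraries stays open, because it was not measured. Antisense reads per base were a median of only 2.39% of those of the sense unit. A loss of Spt5 that lets antisense transcription start or persist stays open as an untested hypothesis. The design cannot separate it from effects of thiamine, NAA or time in culture, which changed together with Spt5.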

How the results depend on the processing

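The alternatives in this part were chosen before the result was seen, and none was added afterwards. The direction of the spt5 fall and of each called unit still tested held with any 1 library left out, with the lone library of a time point assumed to vary like the other groups, but the counts of calls did not hold: they ranged from 1 to 2215 at 2.5 h against 0 h, from 48 to 2186 at 4.5 h and from 0 to 2024 between the times (edgeR; 796 units had an unadjusted p under 0.05 in the fit without replicate 2 of 4.5 h, 1 of the 4 fits with 0 calls). Counts were highest without a 0 h library, and the 2 libraries of 0 h differ most. Because the calls were chosen in these same data, their kept direction is weak support. The spt5 value at 2.5 h ranged from -3.20 to -2.76 and did not pass without replicate 2 of 2.5 h (-2.88).

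With only the 2 time points compared the counts were 420 and 363 for 2.5 and 4.5 h against 0 h. For 4.5 h against 2.5 h the count was 2009. With all 6 libraries they were 908, 932 and 534. The main fit shares an estimate of spread over the time points. The median absolute log2 difference between replicates was 0.37, 0.18 and 0.12 at 0, 2.5 and 4.5 h. The calls against 0 h may thus lean on the tighter later replicates, but the cause of the changed counts was not tested. In the main fit 540, 580 and 289 calls had an absolute log2 fold change of at least 1. At an adjusted p under 0.01 edgeR called 223, 166 and 0 units, where DESeq2 called 776, 794 and 475. For 4.5 h against 2.5 h DESeq2 at 0.05 called 910 and edgeR with library totals 328; the cause was not tested. For 2.5 h against 0 h DESeq2 called 709 higher and 472 lower (60.0% higher, against 70.7%).

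By camera with an estimated correlation 0 list tests and 0 class tests passed, and by fry 12 class tests. The noncoding medians on the log2 CPM scale (1.07, 0.66 and -0.43) and antisense medians (1.45, 0.87 and -0.58) are the same values by construction but not past the threshold with an estimated correlation, nor by fry for the last of each. List tests passed 23 to 44 times with 1 library left out. The shortest quartile of coding units ranged from -0.02 to 0.39 at 4.5 h, reversed at -0.02 without replicate 2 of 0 h. The length relation at 2.5 h ranged from -0.22 to 0.18 and was -0.03 as a Pearson r; it ranged from -0.32 to 0.03 at 4.5 h, and between the times the partial value given level and GC was -0.41; the cause was not tested. The antisense excess over sense partners was 1.39 at 2.5 h with the stricter filter, which drops the lowest units, and ranged from 1.46 to 1.73 at 2.5 h and from 0.93 to 1.19 at 4.5 h. The correlation of the 2 times was 0.35 and 0.45 with no 0 h library in common. Of the 156 values of named units, 1 lost its call with DESeq2, 20 with library totals and 64 with only the 2 time points. With 1 library left out, many combinations of a value and a left-out library lost the call, none with a change of direction.

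Replicates of different times share only a number in the labels. With a replicate block the counts were 977, 1072 and 589, and 7 of the values of named units lost their call; deviations of same-numbered libraries correlated at 0.46, 0.21 and 0.10, which is only a hint from the data. Depth limits the low units: 1 count is worth most in replicate 2 of 2.5 h, with 11525663 counts.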

Other observations

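The grouping of snoRNA units, the choice of the ribosomal RNA unit, its 3 tests and the test of half-life between the 0 h libraries were chosen only after the result was seen.

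Small nucleolar RNAs guide the modification of ribosomal RNA. Of 22 snoRNA units without a coding gene 8 rose and 0 fell at 2.5 h and 10 rose and 0 fell at 4.5 h, with medians of 1.11 and 1.85. Of 15 units that also hold a coding gene 0 rose and 3 fell at 2.5 h and edgeR called 0 at 4.5 h, with medians of -0.27 and -0.10. The difference between the kinds was not tested, and the first kind also differed by a median of 1.58 between the 2 libraries of 0 h. At 2.5 h the first kind moved much as noncoding units did in general, of which 301 of 749 rose (40.2%, median 1.08). At 4.5 h 197 of the 749 noncoding units rose (26.3%, median 0.65), and the difference from snoRNA units was not tested. SPAC9G1.14 had 1.16 and 1.36 normalised CPM at 0 h, 127.9 and 97.96 at 2.5 h and 31.8 and 39.06 at 4.5 h, a log2 fold change of 6.48 at 2.5 h (adjusted p = 0.00095).

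Coding units were also ranked by the deposited synthesis time. In the quartile with the lowest synthesis times, from 2.5 to 4.5 h, 98 of 1112 units rose and 18 fell, with a median of 0.28 and a camera adjusted p of 6.86e-13 (adjusted p = 0.174 with an estimated correlation). In the quartile with the highest 12 of 1107 rose and 160 fell, with a median of -0.29 and a camera adjusted p of 5.3e-08 (adjusted p = 0.2 with an estimated correlation). At 2.5 h against 0 h the directions were the opposite. Both comparisons use the 2.5 h libraries, with opposite sign. A deviation of those libraries alone would give opposite directions, so the reversal is not an independent result. The lowest quartile had 44 rises and 125 falls (median -0.21) and the highest 154 rises and 41 falls (median 0.12). At 4.5 h against 0 h the medians were 0.04 and -0.16. The quartiles were not tested against each other. The lists that passed camera in 0 of the 3 comparisons had medians at 2.5 and 4.5 h of 0.15 and 0.10 for meiotic, 0.39 and -0.10 for glucose-repressed, 0.10 and -0.43 for nitrogen starvation, 0.12 and 0.04 for phosphate, and 0.01 and 0.10 for glycolysis genes. They were -0.06 and 0.21 for respiration, -0.31 and -0.55 for tRNA synthetase, -0.24 and -0.35 for purine and pyrimidine, -0.07 and -0.26 for sterol and lipid, 0.04 and 0.35 for G1/S, and 0.01 and 0.07 for mitosis genes. They were 0.06 and 0.01 for tubulin and spindle, -0.06 and 0.06 for 3' end processing, -0.07 and 0.10 for TFIID, SAGA and Mediator, 0.02 and -0.14 for SCF ligase, and 0.16 and -0.04 for heterochromatin genes. Under some scalings the sign changes for glycolysis, G1/S, mitosis, tubulin and SCF genes at 2.5 h and for meiotic, phosphate, mitosis, tubulin and 3' end genes at 4.5 h. The edgeR median, the log2 CPM mean and camera direction differ in sign for respiration, SCF, TFIID, mitosis and tubulin genes at 2.5 h. They also do so for SCF and glucose-repressed genes at 4.5 h. Median and mean are on different scales here.

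The ribosomal RNA unit TU.3549 (chromosome III, 2439577 to 2448324, plus strand) took 0.722 ± 0.18% of counted reads at 0 h, 3.62 ± 2.0% at 2.5 h and 4.37 ± 1.08% at 4.5 h (SD, n = 2), with log2 fold changes of 2.37 and 2.71. It is 1 of many near-identical copies. A smaller pool of RNA polymerase II transcripts could raise the share of all other RNA, but the table tests only 2 Pol III units, too few to judge. More unlabelled RNA carried over into the treated libraries stays open: the level of long-lived minus short-lived coding units in the highest treated library lay 0.92 above the lowest 0 h library, and the 0 h library with the highest value (0.46) had the lowest ribosomal share (0.595%). Uneven removal of ribosomal RNA cannot be told apart, because 0 units count a spacer apart from the mature RNA.

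The 2 libraries of 0 h differed by gene group, with replicate 1 higher by a median log2 of 2.43 for ribosomal proteins, 1.94 for glycolysis and 1.18 for respiration. The difference went with the deposited half-life across coding units (Spearman rho 0.70, against 0.38 at 2.5 h and 0.05 at 4.5 h), so more long-lived RNA in replicate 1 is a candidate explanation. GC content, unit length and level together explained 15.4% of its variance and stay open as a part. No biological explanation was tested, since the labels put both libraries in 1 group.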
